A study of Homo sapiens with 12 samples.

How the data were processed

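RNA was measured by sequencing of polyA RNA in 12 libraries from the breast cancer lines HCC70 and MDA-MB-231 after 4 h in 100 nM dexamethasone or in ethanol vehicle. Libraries were grouped by line and treatment as the labels give them, 4 groups of 3. The deposited table holds whole-number read counts per gene, which the authors did not scale between libraries. Reads were mapped to hg19 and TopHat 1.4.1, Cufflinks 1.3.0 and bedtools were used, per the submitters' processing notes, which do not say which tool made the counts. The table has 51838 genes in 12 columns, all matched to a library; 11496 genes had no count in any library. The available gene annotation is on another build than hg19, so no coordinates are given; it served only for GC content, length, gene type and exon overlap, and 25272 of the tested genes (89.8%) have a GC value. Genes were kept under the identifiers of the table, since 1458 tested entries share a symbol with another.

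Total counts per library ran from 106345287 to 123218973. A count of 3 over a group, the limit a count of 0 allows, corresponds to 0.00782 to 0.00898 CPM (counts scaled to a library of 1e6), and this covers counting error only. Folds against a group with 0 counts are given as lower bounds from that limit.

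Counts were scaled by TMM and filtered with filterByExpr (minimum count 10) in edgeR 4.0.16 (R 4.3.3), which left 28141 genes, 15229 of them protein coding. A quasi-likelihood model with a mean per group was fitted to all 12 libraries (robust, 8 residual degrees of freedom, prior degrees of freedom 5.64). It was tested two-sided for dexamethasone against vehicle in each line, for the difference of these responses (HCC70 minus MDA-MB-231), and for HCC70 against MDA-MB-231 in vehicle. Adjusted p-values are Benjamini-Hochberg values over all tested genes with a threshold of 0.05. Reported CPM are means with SD over the 3 libraries of a group, scaled by the TMM factors. Genes that passed in both lines were compared by Fisher's exact test, two-sided; the responses share no control libraries.

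The 20 gene lists, written before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a contrast. The comparisons, their main tests, the lists and the rule for named genes were all chosen at that time. Some tests of explanations were chosen later, as stated with them. For each dexamethasone contrast the rule takes the 12 largest rises and 12 largest falls among genes that passed, with a mean log2 CPM of at least 1 and all treated libraries on the same side of all vehicle libraries. It adds up to 4 passing members per list and contrast (2 members with the highest level where none passed), 8 genes per direction for the difference of the responses and for the vehicle comparison, 10 shared genes per direction, 5 genes per direction that changed in opposite ways, and NR3C1, STAT3, FKBP5, TSC22D3 and PER1. Some genes that the rule takes are not reported.

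The scripts were tested on simulated data drawn from the means and library sizes of the real samples, with changed genes of known fold. In HCC70 (27694 genes) 88.2% of 1.5-fold rises, 98.5% of 2-fold and 100% of 4-fold changes were recovered, and 1.57% of calls were false. In MDA-MB-231 (27726 genes) these shares were 76.5%, 98.5% and 100%, with 31.8% false calls, and 9.39% when that line was fitted alone (25387 genes). For the difference of the responses (27679 genes) they were 47.1%, 94% and 100%, with 10.8% false calls, and for the vehicle comparison (27290 genes) 67.6%, 95.5% and 98.5%, with 10.4% false calls. All the 1.5-fold shares cover rises only, since 1.5-fold falls were left out of the scoring. In each comparison the recovered shares rest on 34 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. These were drawn from genes of at least 1 CPM. False shares depend on how many genes were made to change, so they do not carry over to the real counts. All shares given so far come from data without a GC trend. With a trend added that ran with treatment, of a size not fitted to the real libraries, 98.4% of calls were false in HCC70 without correction and 3.19% with it (27757 genes), and 98.5% and 46.5% in MDA-MB-231 (27717 genes). In the simulated HCC70 comparison, where list tests were run, the list made to rise was called by camera and by fry, which also called 0 and 2 of 19 random lists.

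Alternatives planned before the data were examined were other scalings (DESeq2 1.42.0 size factors, upper quartile, library size only), no low-count filter and a strict one (5 CPM in 3 libraries), the DESeq2 Wald test, limma voom, no robust fit, the replicate number as a block, each line fitted alone, each library left out, and for lists an estimated correlation, fry and a smaller prior count. Chosen after the data were seen were an offset that removes GC content and length trends, that offset with the block and with each line alone, genes of at least 1 CPM only, and leaving out MDA-MB-231 vehicle 1 and dexamethasone 2. The labels do not say what the replicate numbers mean, so the main test has no block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.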

Results

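RNA was sequenced from 2 human breast cancer cell lines of the basal-like subtype, HCC70 and MDA-MB-231, after 4 h with 100 nM dexamethasone or with the ethanol it was dissolved in. Dexamethasone is a synthetic glucocorticoid. It activates the glucocorticoid receptor, a transcription factor encoded by NR3C1. The stated purpose was to find the genes under the control of this receptor and of STAT3, a transcription factor switched on by cytokine receptors. Each line and treatment had 3 libraries, 12 in all, with total gene counts of 106345287 to 123218973 per library. At this depth 3 counts over a group correspond to 0.00782 to 0.00898 CPM (TMM-scaled counts per 1e6 counts), a limit that covers counting error only. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. HCC70 was grown in RPMI and MDA-MB-231 in DMEM, so line and medium cannot be told apart in any comparison between the lines.

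The question in HCC70 was which genes respond to dexamethasone. FKBP5 (ENSG00000096060.8), a co-chaperone that restrains the receptor's own activity, rose 6.2-fold, from 35.2 ± 1.1 CPM in vehicle to 218 ± 1.8 CPM (SD, n = 3). PER1, a core clock gene, rose 7.33-fold and SGK1, a kinase named for its induction by glucocorticoids, rose 5.05-fold. TSC22D3, which encodes the anti-inflammatory protein GILZ, rose 2.7-fold from 152 ± 4.8 CPM. HSD11B2 (ENSG00000176387.4), the enzyme that inactivates cortisol, rose 7.58-fold, from 30.9 ± 1.3 to 234 ± 7.6 CPM. The transcription factor TFCP2L1 rose 9.33-fold, from 43.1 ± 1.3 to 402 ± 11 CPM.

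In HCC70 the 12 largest rises among genes with a mean log2 CPM of at least 1 also included IL6R, the interleukin-6 receptor (log2 fold change 2.12 ± 0.12, SE), and BIRC3, an inhibitor of apoptosis (2.09 ± 0.078). They further included the transcription factor KLF9 (3.42-fold), the netrin receptor UNC5B, the prostaglandin transporter SLCO2A1 and SH3TC1. The adjusted p-values of the named genes ran from 8.81e-12 for TFCP2L1 to 8.75e-05 for UNC5B (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). In each all 3 treated libraries lay above all 3 vehicle libraries, which the rule for picking the largest rises required. The falls picked in the same way were smaller. PDE4B, a phosphodiesterase that degrades cyclic AMP, fell 2.87-fold (log2 fold change −1.52 ± 0.14, adjusted p = 1.62e-05), and the related PDE4D fell 1.88-fold. PDGFRA, a receptor for platelet-derived growth factor, fell 2.35-fold, the alarmin IL33 2.29-fold, PPP1R3C, a regulator of glycogen storage, 2.25-fold, and ID4, an inhibitor of basic helix-loop-helix factors, 1.97-fold. NR3C1 itself measured 56.6 ± 3.4 and 52.1 ± 1.5 CPM (adjusted p = 0.346) and STAT3 189 ± 6.6 and 193 ± 3.1 CPM (adjusted p = 0.854), differences that did not pass the edgeR test.

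Gene lists fixed before the data were examined were then compared with all other genes by camera. Of 30 canonical targets of the glucocorticoid receptor, 17 rose and 1 fell in HCC70 (18 and 2 adjusted over the list alone; camera adjusted p = 2.41e-25). DUSP1, a phosphatase that inactivates MAP kinases, rose 2.48-fold, PDK4, a kinase that limits glucose oxidation, 3.91-fold, and ANGPTL4, an inhibitor of lipoprotein lipase, 2.82-fold. The member that fell was TNFAIP3, whose exons overlap another gene (log2 fold change −0.39 ± 0.10, adjusted p = 0.0484), and that call ended without vehicle 1 (adjusted p = 0.138), vehicle 2 (0.112), vehicle 3 (0.126), dexamethasone 2 (0.2) or dexamethasone 3 (0.152). Of 25 STAT3 pathway genes, 8 rose and 0 fell (10 and 3 adjusted over the list alone; camera adjusted p = 3.35e-05); besides IL6R they included NAMPT, a NAD-synthesizing enzyme (log2 fold change 1.00 ± 0.065), and MCL1, a survival factor (0.51 ± 0.060), whose exons overlap another gene. Of 24 apoptosis regulators, 8 rose and 1, the death ligand TNFSF10, fell (11 and 2 adjusted over the list alone; camera adjusted p = 4.9e-05). Those that rose included both inhibitors of apoptosis, such as BIRC3, and the pro-apoptotic BMF, which rose 1.74-fold.

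Of 28 interferon-stimulated genes, 9 fell and 0 rose in HCC70 (12 and 0 adjusted over the list alone; camera adjusted p = 1.64e-06). IFIT1, an antiviral RNA-binding protein, fell 1.53-fold (log2 fold change −0.61 ± 0.086), and DDX58, the viral RNA sensor RIG-I, fell 1.35-fold. Of 21 basal epithelial markers, 4 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 4.9e-05), namely TRIM29 (log2 fold change 0.98 ± 0.083), the keratin KRT15 (0.84 ± 0.090), the desmosomal cadherin DSG3 (0.80 ± 0.072) and the caveolar protein CAV1 (0.53 ± 0.058). These 5 lists also passed camera with an estimated correlation, with adjusted p = 0.00013 for the receptor targets, 0.0156 for the STAT3 genes, 0.0114 for both the apoptosis and the basal list, and 0.0189 for the interferon list.

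Another 6 lists passed camera in HCC70 at the preset correlation only. Of 9 metallothioneins, small metal-binding proteins, 4 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 5.99e-05, adjusted p = 0.0576 with an estimated correlation), among them MT2A (1.6-fold) and MT1X (1.49-fold), both also among the receptor targets. Of 32 matrix, adhesion and proteolysis genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone; 6.6e-05, adjusted p = 0.0628 with an estimated correlation), with PLAT, the tissue plasminogen activator, among the rises (2.03-fold). Of 24 YAP and TEAD targets, 6 rose and 2 fell (8 and 2 adjusted over the list alone; 0.0253, adjusted p = 0.24 with an estimated correlation), with FJX1 and the coagulation starter F3 (tissue factor) among the rises; that call ended without dexamethasone 1 (adjusted p = 0.0874), and without vehicle 1 and dexamethasone 2 of the other line (0.0598), a setting chosen after the data were seen. Of 25 metabolic genes, 5 rose and 1 fell (7 and 3 adjusted over the list alone; 0.0175, adjusted p = 0.157 with an estimated correlation), and HK2, the hexokinase that starts glycolysis, rose 1.53-fold. Of 22 luminal epithelial markers, 5 rose and 0 fell (5 and 2 adjusted over the list alone; 0.0175, adjusted p = 0.304 with an estimated correlation), led by the keratin KRT19 (1.64-fold). Of 29 cell cycle genes, 1 rose and 2 fell (1 and 5 adjusted over the list alone; 0.0175, adjusted p = 0.39 with an estimated correlation), a list call that ended without dexamethasone 3 (adjusted p = 0.0566).

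The remaining 9 lists did not pass camera in HCC70. Of 27 immediate early and MAP kinase feedback genes, 6 rose and 5 fell (8 and 5 adjusted over the list alone; adjusted p = 0.225); the transcription factors FOS (2.95-fold), JUN (1.72-fold) and FOSL2 (1.73-fold) rose and IER3, an immediate early gene, fell 1.57-fold. Rises and falls numbered 3 and 5 of 30 TGF-beta family genes (6 and 7 adjusted over the list alone; adjusted p = 0.725), where BMP2, a secreted growth factor, rose 4.37-fold from 0.433 ± 0.016 CPM. They were 3 and 2 of 24 NF-kB regulators (4 and 2 adjusted over the list alone; 0.392), where the NF-kB inhibitor NFKBIA rose 1.9-fold, 1 and 1 of 25 cytokines (1 and 3; 0.725), and 3 and 0 of 18 clock genes (3 and 2; 0.603). Of 20 acute phase genes 2 rose (3 rose and 2 fell adjusted over the list alone; 0.361), among them the protease inhibitor SERPINA3, from 209 ± 6.2 to 451 ± 23 CPM. Of 22 stress response genes 3 rose (4 adjusted over the list alone; 0.725), of 24 steroid receptors and cofactors 1, HSD11B2, rose (1; 0.64), and of 20 mesenchymal markers 2 rose and 1 fell (2 and 1; 0.263). Without dexamethasone 2 the mesenchymal list passed camera (adjusted p = 0.0201). The mean change of the steroid receptor list was above 0 (0.102 in log2) while its median (−0.052) and its test pointed down; the NF-kB, clock, TGF-beta and stress lists had medians below 0 and means and tests above it.

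Over the 28141 genes tested, dexamethasone changed 1114 in HCC70, 719 up and 395 down (edgeR quasi-likelihood, adjusted p under 0.05), of which 141 rose and 43 fell at least 2-fold. The count was 510 without vehicle 1, 594 without vehicle 2, 587 without dexamethasone 1, 603 without dexamethasone 2 and 610 without dexamethasone 3, and 4828 when the 6 HCC70 libraries were fitted alone. It was 1679 with the DESeq2 Wald test, and 3867 without MDA-MB-231 vehicle 1 and dexamethasone 2, which share the fit. In simulated HCC70 data 1.57% of calls were false, but 98.4% with a GC trend added and 3.19% once that trend was corrected. The size of that simulated trend was not fitted to the real libraries. False shares also depend on how many genes were made to change, so none of these shares carries over to the real counts. Scaling by library size only gave 552 rises and 762 falls, and a stricter filter on low counts 607 and 565. Fold changes in HCC70 correlated with GC content across 13761 genes (Spearman's rho = 0.514; genes are not independent replicates). Each library's deviation correlated with GC content negatively in the vehicle libraries (−0.616, −0.32 and −0.157) and positively in the treated ones (0.509, 0.392 and 0.373). With that trend removed, a correction chosen after the data were seen, 1355 genes rose and 611 fell, 1966 in all, and the luminal list no longer passed (adjusted p = 0.145). The share of counts from mitochondrial genes was 4.59 ± 0.199% in vehicle and 3.59 ± 0.0656% after treatment (SD, n = 3), and that from histone genes 0.0246 ± 0.00086% and 0.0185 ± 0.00045%.

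**Figure D1:**
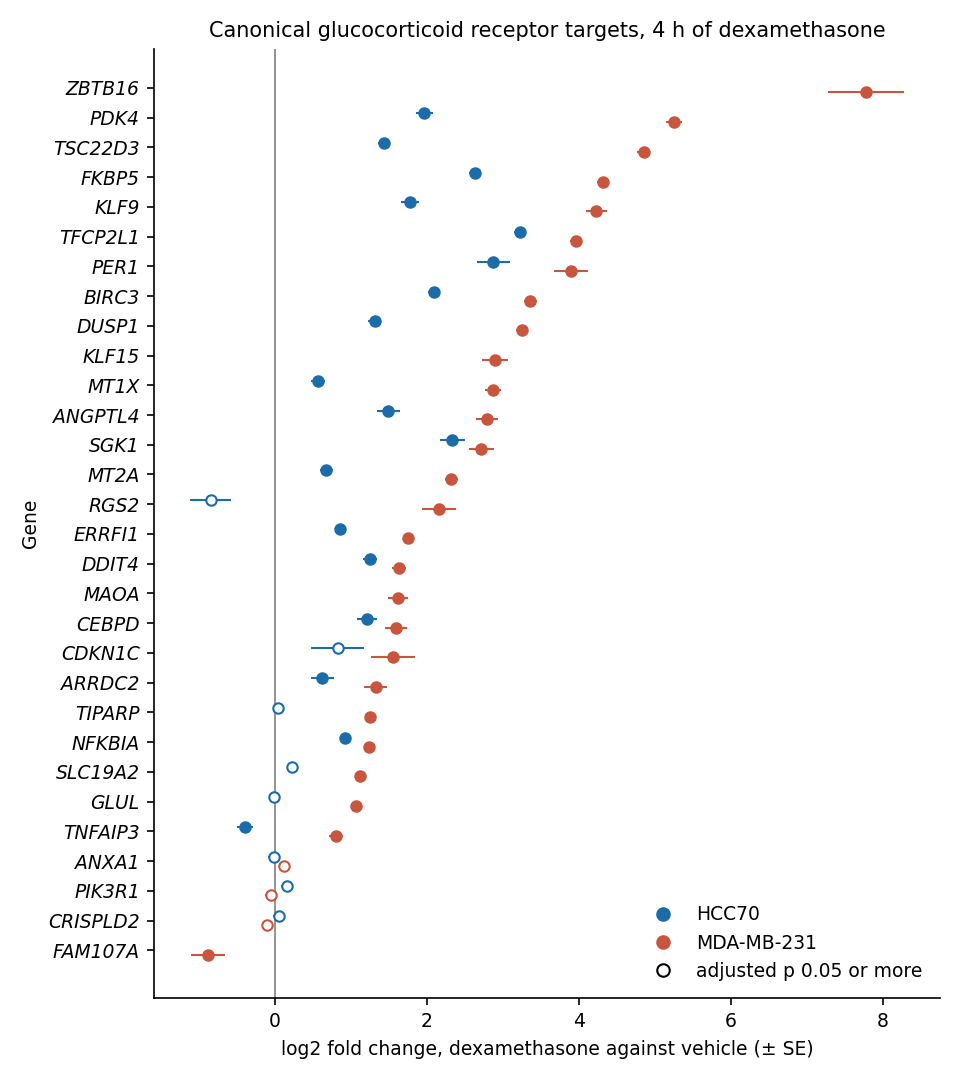
Log2 fold change with its standard error for each of the 30 canonical glucocorticoid receptor targets in HCC70 (blue) and MDA-MB-231 (red), 3 libraries per group; open points did not pass the test, and 4 genes under 0.1 CPM in both HCC70 groups are drawn for MDA-MB-231 only. Most red points lie to the right of the blue ones, with FKBP5 at 6.2-fold in HCC70 and 19.9-fold in MDA-MB-231.

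The same question was put to MDA-MB-231. FKBP5 rose 19.9-fold there, from 56.2 ± 5.5 to 1120 ± 47 CPM, and TSC22D3 28.9-fold, from 5.69 ± 0.64 to 164 ± 4.7 CPM (SD, n = 3). PDK4 rose 38.1-fold, from 3.05 ± 0.39 to 116 ± 7.9 CPM. CEBPB, a transcription factor of inflammatory and metabolic genes, rose 9.39-fold, from 17.1 ± 2 to 160 ± 18 CPM. In the other direction IL11, a cytokine of the interleukin-6 family, fell 13.8-fold, from 23.6 ± 5.1 to 1.71 ± 0.23 CPM, and SOX9, a transcription factor of progenitor cells, fell 4.79-fold, from 108 ± 20 to 22.6 ± 2.8 CPM.

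Further large rises in MDA-MB-231 were FGD4, an exchange factor for the GTPase CDC42 (log2 fold change 4.47 ± 0.070), SGPP2, a sphingosine phosphate phosphatase (4.72 ± 0.19), the vasoconstrictor peptide gene EDN2 (4.67 ± 0.13), KLF9 (4.23 ± 0.14) and NPR3, the clearance receptor for natriuretic peptides (3.92 ± 0.075). PER1 rose 14.9-fold and TFCP2L1 15.6-fold. Adjusted p-values of these 7 genes ran from 6.94e-14 for FGD4 to 9.3e-07 for PER1 (edgeR quasi-likelihood, Benjamini-Hochberg). Further large falls were CX3CL1, a membrane-bound chemokine (6.22-fold), ARTN, a ligand of the RET receptor (5.08-fold), LIPG, endothelial lipase (4.62-fold), ADAMTS1, a secreted metalloprotease (4.56-fold), and FAM46C (4.38-fold). In all of these each treated library lay beyond all 3 vehicle libraries, which the rule for picking the largest changes required. NR3C1 fell 1.41-fold, from 125 ± 9.1 to 88.9 ± 2.3 CPM (adjusted p = 0.000112), while STAT3 measured 135 ± 7.5 and 135 ± 4.8 CPM (adjusted p = 1, edgeR).

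Of the 30 canonical receptor targets, 26 rose and 1, FAM107A, fell in MDA-MB-231 (26 and 1 adjusted over the list alone; camera adjusted p = 1.61e-38). ZBTB16, a transcriptional repressor, went from 0.0163 ± 0.016 to 3.87 ± 1.4 CPM, DUSP1 rose 9.53-fold, BIRC3 10.3-fold and SGK1 6.57-fold. All 9 metallothioneins rose (9 adjusted over the list alone; camera adjusted p = 1.6e-15), with MT1E at 15.1 ± 1.6 and 163 ± 4.3 CPM and MT2A at 48.6 ± 5.2 and 243 ± 5 CPM; values of single members are uncertain because the paralogs are alike in sequence. These 2 lists also passed with an estimated correlation (adjusted p = 2.6e-05 and 0.00426). The remaining calls were lost there.

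Of 27 immediate early and MAP kinase feedback genes, 13 fell and 5 rose in MDA-MB-231 (15 and 5 adjusted over the list alone; camera adjusted p = 0.00015, adjusted p = 0.0988 with an estimated correlation). IER3 fell 3.8-fold, HBEGF, a growth factor that activates the EGF receptor, 3.28-fold, JUN 2.46-fold, FOSL1 2.35-fold and the phosphatase DUSP4 2.35-fold. FOS, at 2.29 ± 0.13 and 1.9 ± 0.15 CPM, did not pass (adjusted p = 0.0517, edgeR). Of 28 interferon-stimulated genes, 10 fell and 1 rose (13 and 1 adjusted over the list alone; 0.000431, adjusted p = 0.0988 with an estimated correlation), among them OASL (1.62-fold), IFIT3 (1.6-fold), IFIT1 (1.51-fold) and DDX58 (1.49-fold). Of 25 STAT3 pathway genes, 11 rose and 6 fell (11 and 7 adjusted over the list alone; 0.0105, adjusted p = 0.1 with an estimated correlation). CEBPB and LIFR, a receptor of the interleukin-6 family (2.5-fold, exons overlapping a non-coding gene), rose, while BCL3, an I-kB family protein, fell 2.4-fold. Of 30 TGF-beta family genes, 12 fell and 6 rose (16 and 6 adjusted over the list alone; 0.0447, adjusted p = 0.131 with an estimated correlation). SMAD7, the pathway's inhibitor, fell 2.52-fold, the growth factor BMP4 2.09-fold, and the receptor TGFBR2 rose 2.15-fold; that list call ended without dexamethasone 1 (adjusted p = 0.077), dexamethasone 3 (0.0511) or vehicle 2 (0.0689), and with a prior count of 0.5 (0.0545).

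The remaining lists did not pass camera in MDA-MB-231, although many of their members did pass the gene test in both directions. Rises and falls numbered 6 and 10 of 24 NF-kB regulators (6 and 12 adjusted over the list alone; adjusted p = 0.283), 7 and 9 of 32 matrix genes (8 and 11 adjusted over the list alone; 0.766), 7 and 6 of 25 metabolic genes (9 and 8; 0.722) and 2 and 7 of 29 cell cycle genes (2 and 8; 0.722). NFKBIA rose 2.36-fold while TNFAIP2, a gene induced by tumor necrosis factor, fell 2.74-fold. PLAUR, the urokinase receptor, fell 2.11-fold. FOXO1, a transcription factor of fasting metabolism, rose 3.64-fold while HK2 fell 1.86-fold. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 3.51-fold. They were 6 and 5 of 24 apoptosis regulators (6 and 8 adjusted over the list alone; 0.935), with TNFSF10 down 2.62-fold, 6 and 5 of 24 YAP targets (6 and 5; 0.959), 5 and 3 of 21 basal markers (5 and 3; 0.766), 2 and 6 of 22 luminal markers (3 and 6; 0.722), and 3 and 4 of 20 mesenchymal markers (4 and 6; 0.96). Among these, the tight junction gene CLDN4 fell 2.75-fold and SNAI2, a repressor of epithelial genes, rose 3.07-fold. Medians below 0 stood beside means and tests above it in the apoptosis, metabolic and basal lists, and in the YAP list only the test pointed up.

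Dexamethasone changed 4110 of the 28141 genes in MDA-MB-231, 1870 up and 2240 down (edgeR quasi-likelihood, adjusted p under 0.05), with 519 rises and 471 falls of at least 2-fold. The count was 2424 without dexamethasone 1, 2463 without dexamethasone 3 and 6452 without dexamethasone 2. It was 2116 when the 6 MDA-MB-231 libraries were fitted alone. HCC70 gave more genes (4828) when fitted alone, so which line changed more genes depends on the fit. Rises outnumbered falls in the 6-library fit of MDA-MB-231 (1110 and 1006), without the low-count filter (1886 and 1782) and with the stricter one (1963 and 1834). In simulated data 31.8% of the calls for MDA-MB-231 were false with the 12-library fit and 9.39% with the 6-library fit. With a simulated GC trend added they were 98.5% before and 46.5% after correction in the 12-library fit. The size of that trend was not fitted to the real libraries either. False shares also depend on how many genes were made to change, so none of these shares carries over to the real counts. Fold changes correlated with GC content across 13761 genes (Spearman's rho = −0.463). The libraries of a group differed in this trend, from −0.249 to 0.7 in vehicle and from −0.532 to 0.283 after treatment. With the trend removed 1885 genes rose and 3269 fell, the TGF-beta list no longer passed (adjusted p = 0.105) and the cell cycle list did (0.0418). Without vehicle 1 and dexamethasone 2, the libraries farthest from their groups in this trend, 5785 genes passed; both settings were chosen after the data were seen.

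**Figure D2:**
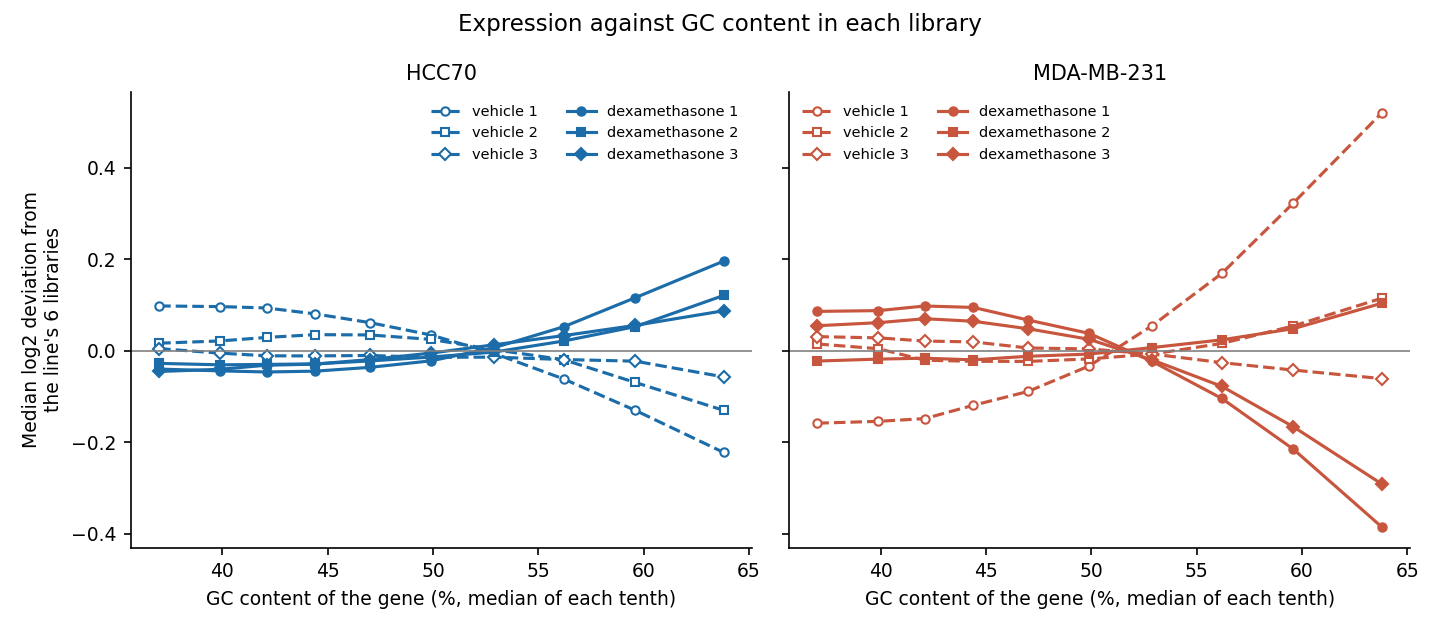
Median log2 deviation of each library from the mean of its line's 6 libraries, for 13761 genes in 10 bins of equal size by GC content (percent), for HCC70 and MDA-MB-231; dashed lines are vehicle and solid lines dexamethasone. The HCC70 vehicle and treated libraries slope in opposite directions (Spearman's rho from −0.616 to 0.509), and MDA-MB-231 vehicle 1 slopes most steeply (0.7).

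**Figure D3:**
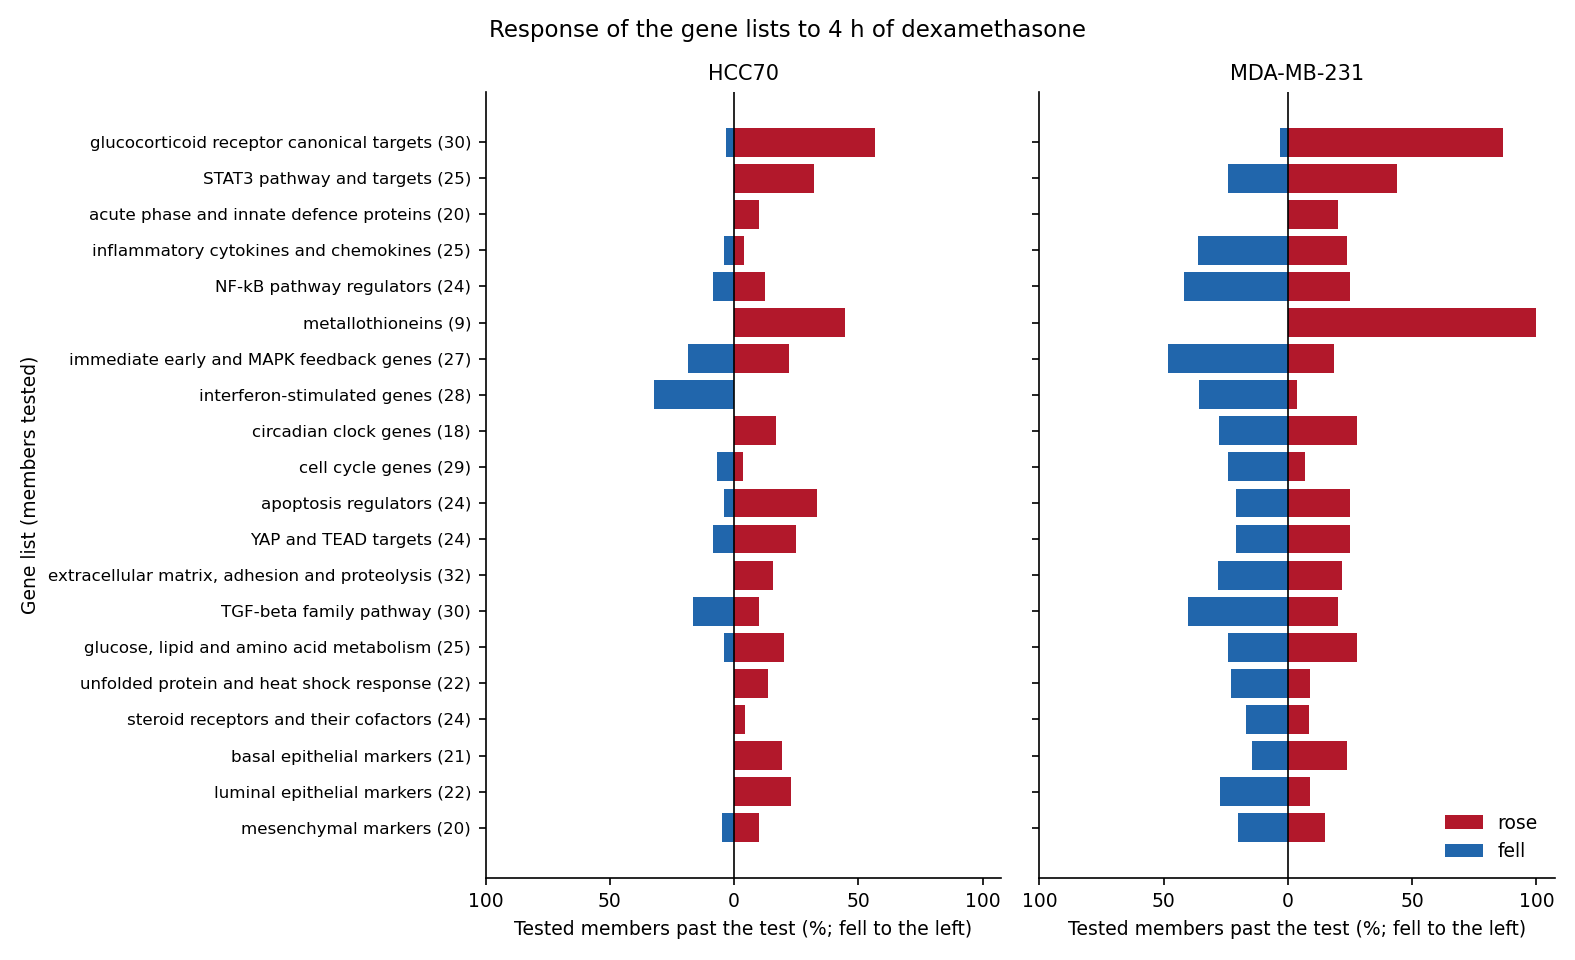
Percentage of tested members of each gene list that rose (red, right) or fell (blue, left) at an adjusted p under 0.05 in HCC70 and MDA-MB-231, with the number of tested members in brackets. Of the 30 glucocorticoid receptor targets 17 rose in HCC70 and 26 in MDA-MB-231, and of the 28 interferon-stimulated genes 9 and 10 fell.

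Comparing the lines shows which responses they share. The shared rises included FKBP5, PER1, TFCP2L1, SGK1 (5.05-fold in HCC70 and 6.57-fold in MDA-MB-231), BIRC3 (4.27-fold and 10.3-fold) and PNMT, the enzyme that makes adrenaline (0.102 ± 0.09 to 1.58 ± 0.22 CPM in HCC70 and 0.114 ± 0.055 to 3.55 ± 0.82 CPM in MDA-MB-231). The shared falls included PDE4B (2.87-fold and 8.67-fold) and ADAMTS1 (1.91-fold and 4.56-fold). In all, 242 genes rose in both lines where independent lists would share 47.8 (Fisher's exact test, odds ratio 8.04, p = 7.13e-107), and 135 fell in both where 31.4 would (odds ratio 6.32, p = 9.44e-51). Genes are not independent replicates, and both lists come from 1 fit in which the lines share each gene's spread. The p-values do not allow for this. Of the 377 shared genes, 252 had the larger estimated change in MDA-MB-231, a count without a test of the difference. It depends on how genes are picked. Among genes of at least 1 CPM, 259 of 793 called in HCC70 and 2680 of 2859 called in MDA-MB-231 changed more in MDA-MB-231. The total of 377 became 239 without HCC70 vehicle 1 and 247 without HCC70 dexamethasone 1. With the GC trend removed it was 658, 415 up and 243 down. With each line fitted alone it was 442. In those fits 282 genes rose in both lines where independent lists would share 121, and 160 fell in both where 62.7 would.

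**Figure D4:**
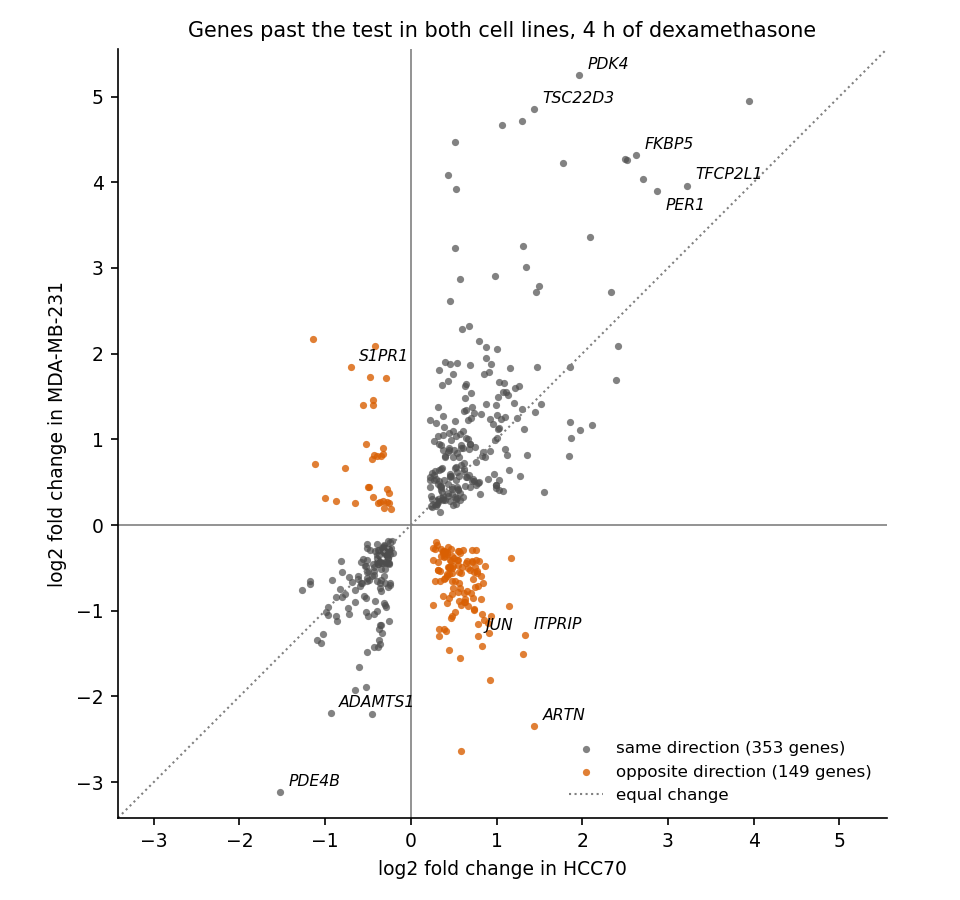
Log2 fold change in HCC70 against MDA-MB-231 for 502 genes that passed the test in both lines and had at least 0.1 CPM in each group, 353 of them changed in the same direction (grey) and 149 in opposite directions (orange); 31 further genes below that level are not drawn. Points above the dotted line on the right, such as PDK4 and TSC22D3, rose more in MDA-MB-231.

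The difference between the 2 responses was tested as an interaction. Canonical receptor targets rose by a larger fold in MDA-MB-231, though 4 of them were under 0.1 CPM in both HCC70 groups. Of the 30, 17 had a larger response in MDA-MB-231 and 0 a larger response in HCC70 (20 and 0 adjusted over the list alone; camera adjusted p = 2.14e-19, adjusted p = 0.000358 with an estimated correlation). TSC22D3, with 26.7 times more transcript in HCC70 vehicle, differed by −3.42 ± 0.10 in log2 response (HCC70 minus MDA-MB-231), PDK4 by −3.29 ± 0.15, KLF9 by −2.46 ± 0.18, DUSP1 by −1.94 ± 0.11 and FKBP5 by −1.68 ± 0.098. SGK1 did not pass this test (−0.38 ± 0.23, adjusted p = 0.288). Of 9 metallothioneins, 7 responded more in MDA-MB-231 and 0 in HCC70 (7 and 0 adjusted over the list alone; 4.07e-10, adjusted p = 0.0174 with an estimated correlation), such as MT1E (−3.32 ± 0.14), which was 9.4 ± 1.3 and 10.1 ± 0.76 CPM in HCC70 (adjusted p = 0.594, edgeR).

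Of 27 immediate early and MAP kinase feedback genes, 12 responded higher and 5 lower in HCC70 (13 and 5 adjusted over the list alone; camera adjusted p = 0.000128, adjusted p = 0.124 with an estimated correlation). JUN rose 1.72-fold in HCC70 and fell 2.46-fold in MDA-MB-231, a difference of 2.08 ± 0.18 in log2, and FOSL2 rose 1.73-fold and fell 2.22-fold, a difference of 1.94 ± 0.16. For FOS the difference was 1.83 ± 0.11 (adjusted p = 1.78e-07, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Of 32 matrix genes, 13 responded higher and 5 lower in HCC70 (13 and 5 adjusted over the list alone; 0.00857, adjusted p = 0.276 with an estimated correlation), including PLAUR (1.10 ± 0.10); with the GC trend removed that list did not pass (adjusted p = 0.143). The STAT3 list, with 8 members higher and 7 lower, did not pass (8 and 8 adjusted over the list alone; 0.971), and its test pointed down where its median and mean lay above 0. CEBPB (−2.71 ± 0.16) and LIFR responded more in MDA-MB-231 and IL6R (0.95 ± 0.17) more in HCC70. The remaining lists did not pass either, with adjusted p-values from 0.177 for the basal markers upward.

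Some genes moved in opposite directions. ARTN rose 2.71-fold in HCC70, from 13.1 ± 0.27 to 35.5 ± 1.9 CPM, and fell 5.08-fold in MDA-MB-231, from 37.7 ± 10 to 7.43 ± 1.4 CPM. ITPRIP, which binds the inositol trisphosphate receptor, rose 2.52-fold and fell 2.43-fold, F3 rose 1.66-fold and fell 1.99-fold, HK2 rose 1.53-fold and fell 1.86-fold, and KRT15 rose 1.79-fold and fell 1.6-fold. S1PR1, a receptor for sphingosine 1-phosphate, fell 1.63-fold in HCC70 and rose 3.58-fold in MDA-MB-231, and PPAP2B, a lipid phosphatase, went from 44.6 ± 0.21 to 31.1 ± 0.18 CPM in HCC70 and from 18.4 ± 0.33 to 35.4 ± 1.9 CPM in MDA-MB-231. HSD11B2, which rose in HCC70, measured 0.739 ± 0.22 and 0.885 ± 0.23 CPM in MDA-MB-231 (adjusted p = 0.448); the responses differed by 2.67 ± 0.25 in log2 (adjusted p = 4.29e-05, edgeR). In all 124 genes rose in HCC70 and fell in MDA-MB-231, where independent lists would share 57.2, and 32 did the reverse, where 26.2 would; all 156 passed the interaction test. That total was 76 without HCC70 vehicle 1, 88 without HCC70 vehicle 2, 94 without HCC70 dexamethasone 1, 88 without HCC70 dexamethasone 2 and 97 without HCC70 dexamethasone 3. With the GC trend removed it was 257, with 209 genes that rose in HCC70 and fell in MDA-MB-231, where independent lists would share 157, and 48 that did the reverse, where 40.9 would. It was 267 with the DESeq2 Wald test and 1193 without MDA-MB-231 vehicle 1 and dexamethasone 2. With each line fitted alone it was 225. Of these, 163 rose in HCC70 and fell in MDA-MB-231, where independent lists would share 109, and 62 did the reverse, where 69 would.

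The interaction test called 3391 genes, 1960 with the higher and 1431 with the lower log2 response in HCC70 (edgeR quasi-likelihood, adjusted p under 0.05). The count was 1614 without HCC70 vehicle 1, 1917 without HCC70 vehicle 2, 1850 without HCC70 dexamethasone 1, 2144 without HCC70 dexamethasone 2, 1954 without HCC70 dexamethasone 3, 1827 without MDA-MB-231 dexamethasone 1 and 1755 without MDA-MB-231 dexamethasone 3. It was 5789 without MDA-MB-231 vehicle 3, 6259 without MDA-MB-231 dexamethasone 2, and 6206 without vehicle 1 and dexamethasone 2 of that line together. Scaling by library size only gave 1766 higher and 2498 lower and shifted genes of at least 1 CPM in all groups by a median of −0.113 in log2; the stricter low-count filter gave 46.1% higher, and removing the GC trend 2734 higher and 1241 lower. The fold changes of the difference correlated with GC content (Spearman's rho = 0.557 across 13761 genes).

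**Figure D5:**
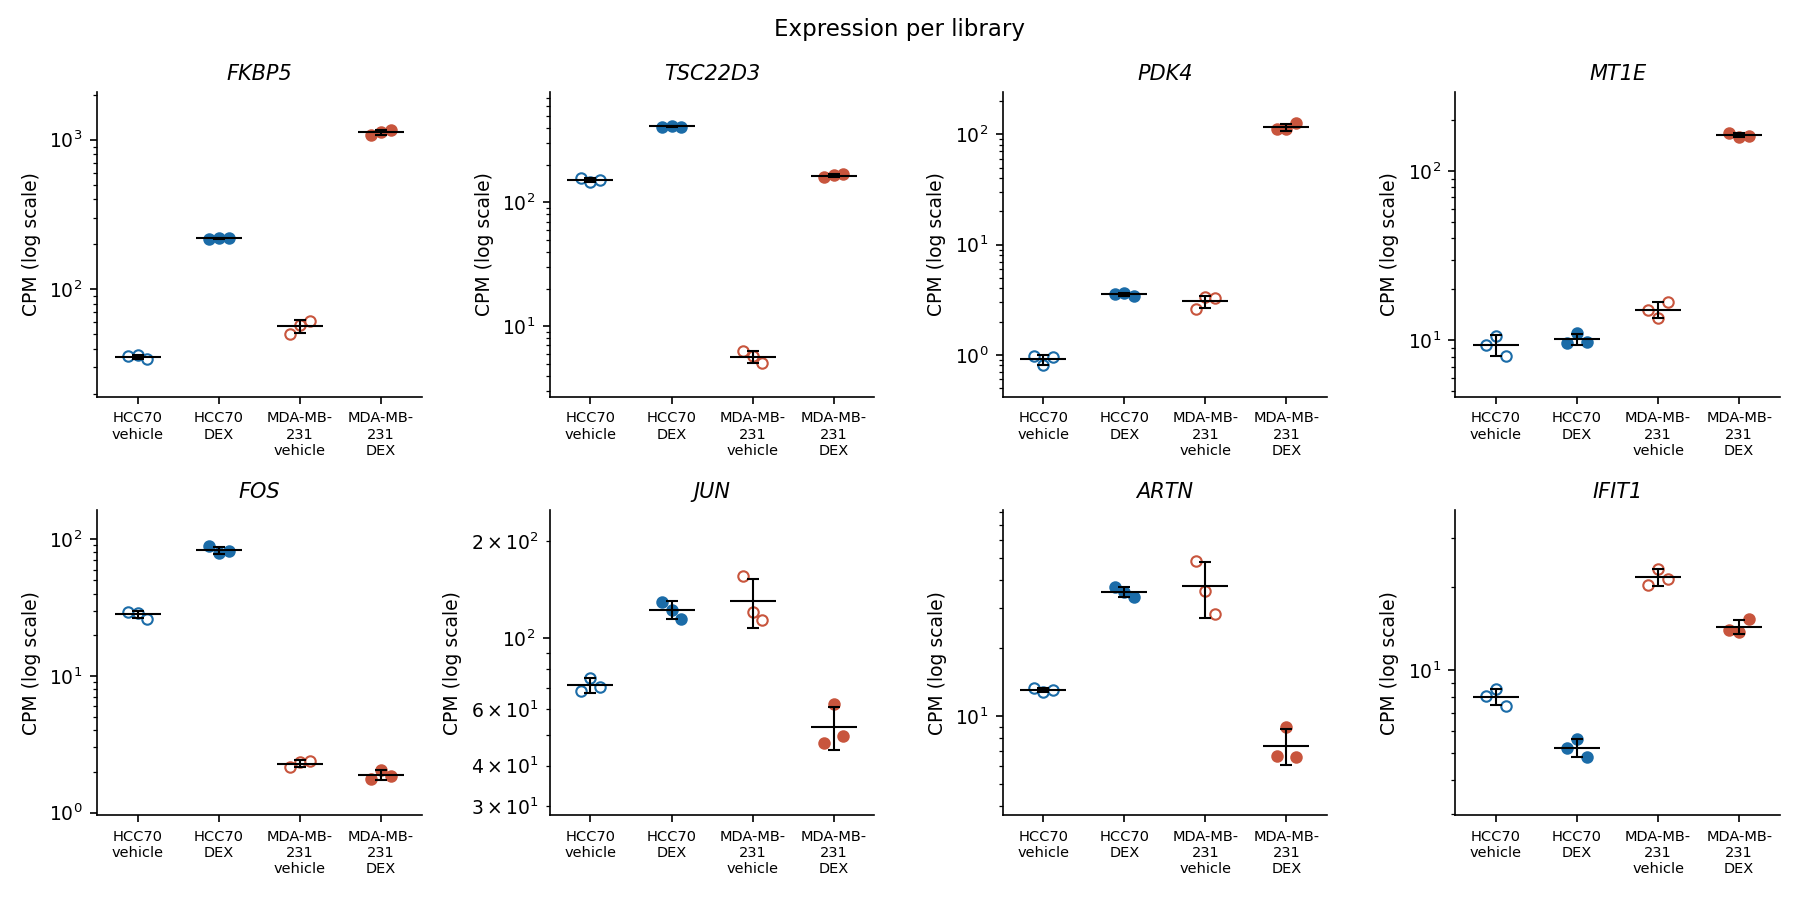
CPM (log axis) in each library of 8 genes in the 4 groups; open circles are vehicle, filled circles dexamethasone, black bars the mean and SD of 3 libraries. FKBP5 goes from 35.2 to 218 CPM in HCC70 and from 56.2 to 1120 CPM in MDA-MB-231, while ARTN goes from 13.1 to 35.5 and from 37.7 to 7.43 CPM.

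In vehicle the lines differed in most genes. KRT5, a basal keratin, was at 2600 ± 130 CPM in HCC70 and 0.804 ± 0.44 CPM in MDA-MB-231, and CDH3, P-cadherin, at 649 ± 19 and 0.414 ± 0.095 CPM (SD, n = 3). AXL, a receptor tyrosine kinase of mesenchymal cells, was at 0.0483 ± 0.033 CPM in HCC70 and 1850 ± 360 CPM in MDA-MB-231, and TIMP3, an inhibitor of metalloproteases, at 0.0577 ± 0.032 and 374 ± 30 CPM. CDH11, a mesenchymal cadherin, had 0 counts in HCC70 and was at least 14600-fold higher in MDA-MB-231, and CDKN2B, a cell cycle inhibitor, had 0 counts in MDA-MB-231 vehicle and was at least 10200-fold higher in HCC70 (floor of 3 counts over the group). NR3C1 was 2.22-fold higher in MDA-MB-231, 125 ± 9.1 against 56.6 ± 3.4 CPM (adjusted p = 6.97e-10), and STAT3 1.4-fold higher in HCC70 (adjusted p = 2.5e-06, edgeR quasi-likelihood).

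Of 22 luminal markers, 21 were higher and 1 lower in HCC70 (camera adjusted p = 1.43e-07), including RAB25, an epithelial trafficking GTPase, at 92.8 ± 3.2 and 0.0159 ± 0.02 CPM. Of 21 basal markers, 16 were higher and 3 lower (0.000624), and of 20 acute phase genes, 15 were higher and 5 lower (0.00151), among them S100A9, a calprotectin subunit with 0 counts in MDA-MB-231 vehicle and at least 4430-fold higher in HCC70. Of 24 YAP and TEAD targets, 1 was higher and 20 lower in HCC70 (2.51e-07), such as DLC1, which had 0 counts in HCC70 vehicle and was at least 12300-fold higher in MDA-MB-231. These 4 lists passed with an estimated correlation (adjusted p = 0.0407, 0.0347, 0.0358 and 0.0347 in that order). Further lists passed at the preset correlation only. Mesenchymal markers were 3 higher and 15 lower in HCC70 of 20 (0.000624, adjusted p = 0.095 with an estimated correlation), matrix genes 7 and 23 of 32 (0.000624, adjusted p = 0.095 with an estimated correlation), and immediate early genes 5 and 20 of 27 (0.000624, adjusted p = 0.095 with an estimated correlation), with FOSL1 124-fold and DUSP4 88.4-fold lower. Interferon-stimulated genes were 19 higher and 6 lower of 28 (0.0064, adjusted p = 0.141 with an estimated correlation) and clock genes 11 and 4 of 18 (0.0361, adjusted p = 0.148 with an estimated correlation). For these 9 lists the counts adjusted over the list alone were the same. The remaining 11 lists did not pass, among them the receptor targets with 10 higher and 17 lower of 30 (10 and 17 adjusted over the list alone; adjusted p = 0.292) and the STAT3 genes with 12 and 12 of 25 (12 and 12 adjusted over the list alone; 0.939).

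In all 22294 of 28141 genes (79.2%) differed between the lines in vehicle, 11037 higher and 11257 lower in HCC70 (edgeR quasi-likelihood, adjusted p under 0.05); 11980 passed under the stricter low-count filter, which tests fewer genes. Summed over 9 epithelial markers, HCC70 had 4430 CPM and MDA-MB-231 70.3 CPM in vehicle, and over 7 mesenchymal markers 862 and 4990 CPM. Markers of other cell types summed to 61.9 and 69.9 CPM over 14 leukocyte and 9.78 and 93 CPM over 9 endothelial markers. Over 11 fibroblast markers the sums were 79.4 and 72.1 CPM. After dexamethasone they were 67 and 68.7, 10 and 104, and 106 and 43.3 CPM. A few genes made up most of each sum, such as CD14 (36.4 CPM) and COL1A1 (72.1 CPM) in HCC70 vehicle and ESAM (89.4 CPM) in MDA-MB-231 vehicle. KDR, an endothelial marker, went from 2.53 to 21.5 CPM in MDA-MB-231. The sums therefore do not measure how many other cells were present.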

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

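In the results below the effect of dexamethasone differed between the lines in a test of the difference itself. Of the tests, those of the GC trend behind the opposite fold changes, and of the NR3C1 level and the number of members lower in HCC70 vehicle behind the receptor targets, were chosen after the result was seen, and the GC correction and the removal of 2 MDA-MB-231 libraries were chosen after seeing the data.

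The test of the difference called 3391 genes (edgeR). In opposite directions, 124 genes rose in HCC70 and fell in MDA-MB-231 and 32 did the reverse. Lists that differed were the glucocorticoid receptor targets (camera adjusted p = 2.14e-19), metallothioneins (4.07e-10), immediate early genes (0.000128) and matrix genes (0.00857). The call was lost with an estimated correlation by the immediate early genes (adjusted p = 0.124) and the matrix genes (adjusted p = 0.276), and by the matrix genes also with the GC trend removed (adjusted p = 0.143). Among genes with a mean log2 CPM of at least 1 over the 12 libraries, the largest positive differences in log2 response (HCC70 minus MDA-MB-231) with counts in every group were IL11 at 4.24, ARTN at 3.78, CX3CL1 at 3.23, ELF3 at 2.98 (exons overlap other genes), WNT9A at 2.74, HSD11B2 at 2.67 and ITPRIP at 2.62. AUTS2 also passed, with 169 and 185 CPM in HCC70, and in MDA-MB-231 0.051 CPM in vehicle and 0 counts after treatment, at least 6.52-fold lower. Its place among these genes is not known. With the GC trend removed the log2 responses of ARTN were 1.12 in HCC70 and −1.86 in MDA-MB-231, against 1.44 and −2.34 without correction. The size of such differences depends on that correction, and their order may. The largest negative differences among genes of that level were FGD4 at −3.96, C1orf172 at −3.92, SCNN1B at −3.86, EDN2 at −3.61, C5orf62 at −3.56, ACPL2 at −3.54 (exons overlap another gene), TSC22D3 at −3.42 and NPR3 at −3.39.

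Over 14598 genes of at least 1 CPM in all groups, the fold changes of the lines ran in opposite directions (Spearman's rho = −0.322 across genes, which are not independent replicates). After the GC content and length trend of each library was removed rho was −0.0859, so that trend could account for most of it. Whether the trend is technical or part of the response stays open in HCC70, where it separates all vehicle from all treated libraries. Without MDA-MB-231 vehicle 1 and dexamethasone 2 rho was −0.29, which argues against those 2 libraries together as the only cause. Their correlations with GC content (0.7 and 0.283) move the difference between treated and vehicle libraries in opposite ways. They were removed together, so the part of either library alone stays open.

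Receptor targets rose by a larger fold in MDA-MB-231 in 17 of 30 cases. All 17 kept the call after the GC trend was removed, and 17 lay beyond 3 standard errors with errors from each line alone, which argues against that trend and against unequal spread as the cause. Of the 17, 10 were lower and 5 higher in HCC70 vehicle, which argues against a higher vehicle level in HCC70 as the cause for most of them. For the 5 it stays open, since the relation of vehicle level to response over all 30 members (rho = −0.164, r = −0.243, permutation p = 0.384) lay above the limit of −0.2 set beforehand by less than its spread. NR3C1 was lower in HCC70 vehicle (log2 −1.15, adjusted p = 6.97e-10, edgeR), but with 2 lines this cannot be told from any other difference between them.

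Of the 156 genes that changed in opposite directions, 150 kept the call for a different response after the GC trend was removed. Without the 2 MDA-MB-231 libraries 154 kept it. This argues against both as the cause of a different response in most of them. Opposite calls in the lines themselves were kept by 122 with the trend removed, 97 that rose in HCC70 and 25 that fell. The excess of genes that rose in HCC70 and fell in MDA-MB-231 over independent lists was smaller with the trend removed. It was 209 against 157 there and 124 against 57.2 without correction. Whether the trend adds to the number of such genes stays open. With no exon overlap with another tested gene there were 99, which argues against shared reads as the cause of most. A difference between the lines in their response, the biological explanation, cannot be told from the culture medium.

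Real groupings were compared with other groupings of the same libraries. Within a line or within vehicle there are 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 1114 genes in HCC70 (highest other 0), 4110 in MDA-MB-231 (highest other 1562) and 22294 in vehicle (highest other 0), and 11, 6 and 9 lists (highest other 5, 2 and 7). For the difference of the responses, 1 of 100 splits reached 3391 genes, the real one (highest other 3226). For the shared genes 1 of 100 reached 377 (highest other 156). These splits relabel each line separately, so some can keep the real grouping of a single line and with it that line's response. A split can also keep both real groupings with vehicle and dexamethasone swapped in MDA-MB-231. It would count the genes that changed in opposite directions as shared, and these numbered 156, the same as the highest other value. That value therefore need not come from an arbitrary regrouping. For the lists of the difference, 17 of 100 splits gave as many as 4 (highest other 10). Because of such splits, this share cannot tell whether the number of lists could arise by chance.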

How the results depend on the processing

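The GC offset, alone, with the block or with each line alone, the limit to genes of at least 1 CPM and the removal of MDA-MB-231 vehicle 1 and dexamethasone 2 were chosen after seeing the data; the rest was planned. Of the named genes that passed, 100 in HCC70, 119 in MDA-MB-231 and 88 for the difference, none reversed under the settings run, but calls were lost. With the replicate block 24, 9 and 9 were lost, and on leaving out a library 18 to 26, 1 to 14 and 0 to 8. Gene and list counts beyond 1.5 times the reported ones were these, and the cause was not tested unless stated. With the DESeq2 Wald test HCC70 had 1679 genes and 267 went in opposite directions. With a replicate block HCC70 had 481, MDA-MB-231 2551, the difference of the responses 1480, the shared genes 203 and the genes in opposite directions 63 of the reported 156, and the TGF-beta list in MDA-MB-231 lost its call (0.0733). Same-number correlations were −0.254, 0.134 and −0.00882 in HCC70 and −0.66, −0.3 and 0.373 in MDA-MB-231. Of 6 vehicle libraries 1 correlated best with its own number. The highest in MDA-MB-231 joined other numbers, vehicle 1 with dexamethasone 2 (0.77) and vehicle 3 with dexamethasone 1 (0.685). Those libraries also differ in GC trend, so the correlations give no sign of pairs by number but do not settle the question. Each line fitted alone gave 4828 in HCC70 and 2116 in MDA-MB-231, and 4251 in HCC70 with the GC offset. The GC offset gave 1966 in HCC70, 658 shared and 257 opposite; with it the cell cycle list in MDA-MB-231 (0.0418) and the steroid receptor list in vehicle (0.0439) passed. Without the 2 MDA-MB-231 libraries HCC70 had 3867, the difference 6206 the shared genes 654 and the opposite ones 1193. The strict filter gave 11980 in vehicle, since fewer genes were tested. Leaving out each library gave 510 to 810 in HCC70, 2424 to 6452 in MDA-MB-231, 1614 to 6259 for the difference 239 to 372 shared and 76 to 189 opposite; vehicle stayed within 21711 to 22339. Lists called with an estimated correlation were 5 in HCC70, 2 in MDA-MB-231, 2 for the difference and 4 in vehicle; with fry they were 11, 11 and 19 in the last 3. In vehicle fry gave the other direction than camera for the cell cycle genes (1.39e-06) and the TGF-beta family (0.0079). Lists ranged from 10 to 12, 5 to 6, 4 to 4 and 9 to 9 when a library was left out. Depth limits values under 3 counts over a group.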

Other observations

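Hypotheses below were written before their results were seen. Inflammatory cytokines moved in both directions in MDA-MB-231, with 6 that rose and 9 that fell of 25 (7 and 9 adjusted over the list alone; camera adjusted p = 0.766). PTGS2, the inducible prostaglandin synthase, rose 5.91-fold and the neutrophil chemokine CXCL2 5.05-fold, while IL11 fell 13.8-fold and CX3CL1 6.22-fold. Of 18 clock genes 5 rose and 5 fell (5 and 6 adjusted over the list alone; 0.935). PER1 rose 14.9-fold and the clock repressor gene C1orf51 3.86-fold, while HLF, a clock-controlled transcription factor, went from 0.398 ± 0.026 to 0.159 ± 0.024 CPM (SD, n = 3).

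Of 20 acute phase genes 4 rose and 0 fell in MDA-MB-231 (4 and 0 adjusted over the list alone; camera adjusted p = 0.115), among them SERPINA3 (2.93-fold, from 0.534 ± 0.17 CPM). Stress response genes were 2 up and 5 down of 22 (2 and 5 adjusted over the list alone; 0.973), and steroid receptors and cofactors 2 up and 4 down of 24 (3 and 4 adjusted over the list alone; 0.959), NR3C1 among the falls. In the cytokine and clock lists the mean lay above 0 and the test pointed down, and in the stress and steroid receptor lists the mean lay below 0 and the test pointed up.

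One hypothesis was that genes with less transcript in vehicle rise more. Over the 242 genes that rose in both lines, the vehicle difference (replicate 1) and the response difference (replicates 2 and 3) had Spearman's rho = −0.206 (permutation p = 0.00113, across genes, which are not independent replicates) and r = −0.306. Without the 2 genes farthest on the vehicle difference they were −0.188 and −0.286. This fell between the limits set beforehand and does not decide the hypothesis. Over the 11361 genes called in neither line, with at least 1 CPM in all 4 groups, rho was −0.0525.

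Another was that the interferon-stimulated genes that fell are shared by the lines. Of 28 members 9 fell in HCC70 and 10 in MDA-MB-231. In both lines 7 fell, where independent calls would give 3.21 (Fisher's exact test, two-sided, p = 0.00278, across genes, which are not independent replicates). This fits the hypothesis, but falls over all genes were shared beyond independent lists too (odds ratio 6.32). The 7 were IFIT1, IFIT2, IFIT3, OASL, DDX58, IRF1 and RSAD2, of which IFIT2, IRF1 and RSAD2 have exons that overlap another gene.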
